A study of Verbena bonariensis with 6 samples.

How the data were processed

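RNA was measured in roots of 2-month-old Verbena bonariensis plants, with 3 control libraries (no cadmium solution added) and 3 cadmium libraries (100 mg/kg, 20 days). Per the labels' protocols, roots were frozen in liquid nitrogen, RNA was extracted with Trizol, and libraries were made with an Illumina TruSeq RNA kit. The hour of harvest is not given in the sources used here. The submitters' processing notes name Bowtie2 2.0.6 and TopHat2 2.0.12. Their role, the assembler, if any, and the counting tool are not given in the sources used here.

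The values of the 8544 deposited lines cover 8147 gene clusters in 79 families of transcription factors and other regulators, with 84 clusters in more than 1 family and 387 clusters at 0 in every library. Expected counts per cluster and library, read counts per the file headers, were deposited by the authors without scaling to depth, and many have decimals. FPKM values per cluster and library were made by the authors before deposit, per the file headers, and checked here to follow count, length and a constant per library. The deposited log2 ratio of cadmium over control was made by the authors, per the file headers, and lay 0.0939 (median, SD 0.0114 over 1196 clusters) above the log2 ratio of mean counts. The deposited q-value of that comparison was also made by the authors, per the file headers, with a test that is not given in the sources used here. Names are those of the best Swiss-Prot hit (7508 clusters, 1369 proteins), otherwise of the best hit in the NR protein database (8051 clusters, 2566 proteins, 5999 clusters with a best hit in sesame, Sesamum indicum). Reads of near-identical clusters could be split between them by the counting, so values of single clusters are uncertain to that extent.

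Expected counts were rounded to whole numbers. Library totals, needed because these regulators are a part of each library, were recovered by fitting count over FPKM against cluster length, over clusters above 300 counts and 10 FPKM. Table totals and recovered totals per library are given as ranges in the results. With a floor of 3 counts over a group, a group at 0 gives a bound on the fold, which covers counting error only.

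The comparison of 3 cadmium with 3 control libraries used edgeR 4.0.16 in R 4.3.3: filterByExpr by group (minimum count 10, minimum total 15), TMM scaling within the regulators, a quasi-likelihood fit with group as the only term, and Benjamini-Hochberg adjustment at 0.05, with a second count at an absolute log2 fold change of at least 1. SE is the log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.573. CPM are scaled to the total counts of the regulators in each library after TMM. Groups of clusters were tested with camera (limma 3.58.1) on log2 CPM (prior count 2, preset correlation 0.01, and again with an estimated correlation) and with fry: fixed word lists with at least 5 tested clusters, families with at least 10, and GO and KEGG terms with 10 to 500. Camera compares a group with the other regulators. Shares of the libraries were compared with exact two-sided permutation tests. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for preparation and figures.

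Named genes followed a rule set before the data were examined, as were the comparison, the lists and most of the other settings tried. It takes the 8 highest and 8 lowest log2 fold changes among changed clusters with a mean of at least 10 counts in the higher group, groups that do not overlap and a described function. From each list and family it adds up to 2 clusters higher and 2 lower with the smallest adjusted p, and clusters with the same description count once. All 67 clusters named with values fall under this rule.

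The fit was tested on simulated counts with 200 clusters changed. Among the 4362 simulated clusters that passed the filter, 63 were changed 2-fold, 61 were changed 4-fold and 52 were changed 8-fold. The fit recovered 9.5% of 2-fold, 39.3% of 4-fold and 67.3% of 8-fold changes, with 6 false among 71 calls (8.5%). A smaller share of clusters changed there than in the data, so these rates need not hold for the data. Camera called a simulated set made up of raised clusters only, and 0 of 40 null sets. Simulated clusters varied independently of each other, so this cannot show how camera does with correlated clusters.

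Other settings set before the data were examined were edgeR's RLE size factors and whole-library totals without TMM. Set with them were no filter, a filter of 5 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1). So were the replicate number as a block, each library left out, sums over the best Swiss-Prot hit, and removal of the cluster with a best NR hit outside plants. Chosen after seeing the data were sums over the best NR protein, scaling to the authors' deposited ratios, leaving out clusters changed over 32-fold before the list and family tests, and every alternative for the families and the leave-one-out fits for terms. Transcripts other than these regulators were not analysed here, so 18 of the 39 lists had no cluster.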

Results

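Root transcripts of Verbena bonariensis, an ornamental garden plant (cultivar Finesse), were measured by RNA sequencing after 20 days in soil with 100 mg/kg cadmium, a toxic metal, and in soil to which no cadmium was added. Each group held 3 libraries, which the labels call biological replicates. The values analysed here cover transcription factors and other transcriptional regulators only: 8147 gene clusters in 79 families. Clusters carry the name of their best database hit where they had one, so several clusters can share a name, and 18 of the 67 clusters named below had another cluster of the same gene symbol changed in the opposite direction. After counts were summed over clusters that share their best protein in the NR database, a step chosen after the data were seen and called NR sums below, 21 of the 67 had a log2 fold change that was reversed or over 1.5 times smaller, and 13 were alone under their protein, so that the sum added nothing. Genes of metal transport, chelation and antioxidant defence outside these regulators were not analysed here. The regulator counts summed to between 1207479 and 1340255 per control library and between 1092183 and 1228042 per cadmium library. The whole libraries, recovered from the counts and FPKM, held 18636091 to 20558908 fragments in the control group and 20390656 to 23343050 in the cadmium group. Regulators took 6.48% ± 0.036 (SD, n = 3) of the control libraries and 5.37% ± 0.152 (SD, n = 3) of the cadmium libraries, with no overlap (exact two-sided permutation test, p = 0.1, the smallest p that 3 against 3 allow). Expression values below are CPM, scaled to the total counts of these regulators in each library, as mean ± SD with n = 3 per group, and log2 fold changes are cadmium against control with the standard error (SE) of the fit.

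The comparison asked which root regulators differ in transcript level under cadmium. The LOB-domain regulator LBD41 rose from 28.4 ± 5.16 to 1480 ± 144 CPM, and the MYB protein RAX3 rose from 98.4 ± 10.9 to 2200 ± 161 CPM. WRKY70 and WRKY28, members of a family best known from defence and stress responses, and ERF106, of the ethylene response factor family, rose by 3.02 ± 0.09, 3.38 ± 0.1 and 2.94 ± 0.07 on the log2 scale (SE, n = 3 per group). In the opposite direction, the jasmonate-response activator MYC2 fell from 9550 ± 357 to 3430 ± 426 CPM and the auxin-response repressor IAA14 from 3030 ± 122 to 967 ± 120 CPM. The heat stress factor HSFA3 fell from 1390 ± 148 to 108 ± 10.1 CPM, and the clock regulator APRR7 from 2160 ± 132 to 25.5 ± 6.4 CPM. All of these differences passed edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p between 1.54e-05 for RAX3 and 0.00023 for MYC2.

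Of 4844 clusters tested, 1476 changed (30.47%), 767 higher and 709 lower in cadmium, and 1033 changed at least 2-fold, 520 higher and 513 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The control and cadmium libraries did not overlap for any of the 1476 clusters. Over all tested clusters, 53.47% showed no overlap, where chance gives 10%. Fold changes are relative to the typical regulator: scaling to whole-library totals shifted the median log2 fold change by −0.347 and gave 527 higher and 1113 lower, so that 32.13% of the changed clusters were higher in place of 51.96%. The authors' deposited table called 1473 clusters at a q-value below 0.05, 689 higher and 784 lower. Of its calls, 1155 were also made here in the same direction and 0 in the opposite direction.

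**Figure D1:**
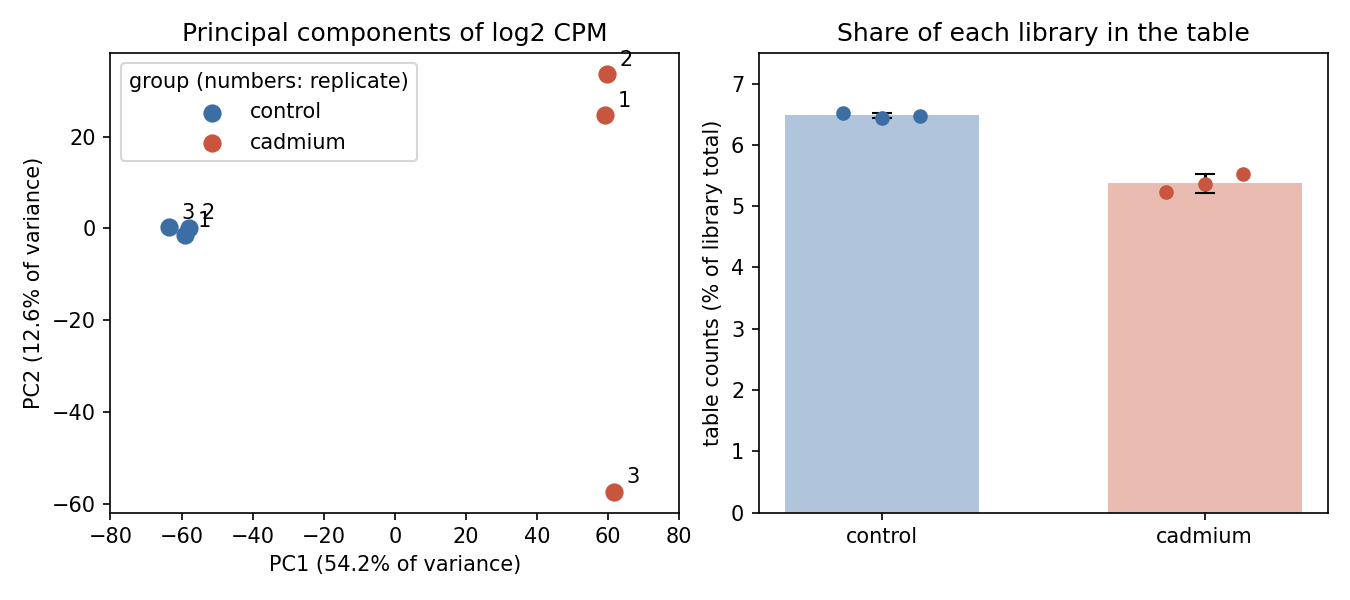
Left, the first and second principal components of log2 CPM for the 6 libraries, with replicate numbers beside the points. The first component, with 54.2% of the variance, separated the groups, and cadmium replicate 3 lay apart from the other cadmium libraries on the second, with 12.6%. Right, regulator counts as a percentage of each library's recovered total (points: libraries, bars: means, error bars: SD, n = 3): 6.48% in control and 5.37% in cadmium.

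Among the 61 families with at least 10 tested clusters, 4 moved as groups against the other regulators (camera on log2 CPM, preset correlation 0.01). The LOB-domain family, plant-specific regulators that include lateral root genes, had 35 clusters higher and 8 lower of 79, with a median log2 fold change of 1.11 (camera, Benjamini-Hochberg adjusted p = 0.000212, and adjusted p = 0.364 with an estimated correlation). LBD41 (Cluster-9033.10286) rose by 5.7 ± 0.17 (SE) and LBD42 (Cluster-9033.92365) by 2.03 ± 0.06, from 775 ± 21.3 to 3160 ± 138 CPM. LBD21 (Cluster-9033.162628) fell from 182 ± 25.5 to 33.9 ± 4.11 CPM. The SRS family, zinc-finger regulators of organ development, had 9 clusters higher and 0 lower of 21, with a median of 1.1 (camera, Benjamini-Hochberg adjusted p = 0.00409, and adjusted p = 0.5 with an estimated correlation). Its member SHI RELATED SEQUENCE 1 rose from 236 ± 33 to 696 ± 80.3 CPM. LATERAL ROOT PRIMORDIUM 1 rose from 1180 ± 19.3 to 2010 ± 357 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.00686), but did not pass with whole-library totals (adjusted p = 0.0655).

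The other 2 families moved down. AUX/IAA, the repressors of auxin response, had 5 clusters higher and 28 lower of 91, with a median of −0.79 (camera, Benjamini-Hochberg adjusted p = 0.00409, and adjusted p = 0.364 with an estimated correlation). The smaller KEGG group annotated as auxin-responsive IAA proteins had 4 higher and 18 lower of 60, with a median of −0.48. That group did not pass (camera over annotation terms, Benjamini-Hochberg adjusted p = 0.291). PLATZ, plant-specific zinc-binding regulators, had 0 higher and 5 lower of 20, with a median of −1.35 (camera, Benjamini-Hochberg adjusted p = 0.0211, and adjusted p = 0.5 with an estimated correlation). A PLATZ cluster with no described function (Cluster-9033.60436) fell from 3070 ± 142 to 1290 ± 70.3 CPM. The directions of all 4 family medians were the same with whole-library totals (0.62, 0.62, −1.13 and −1.69). On that scale 31 clusters were higher and 10 lower in LOB, 7 and 1 in SRS, 4 and 38 in AUX/IAA and 0 and 10 in PLATZ. After counts were summed over clusters that share a best protein hit, a step chosen after the data were seen, AUX/IAA passed (30 of 42 proteins lower, camera, Benjamini-Hochberg adjusted p = 0.00399), while LOB (adjusted p = 0.067) and PLATZ (adjusted p = 0.272) did not and SRS had too few proteins. With an estimated correlation AUX/IAA did not pass after these sums (camera, Benjamini-Hochberg adjusted p = 0.734).

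**Figure D2:**
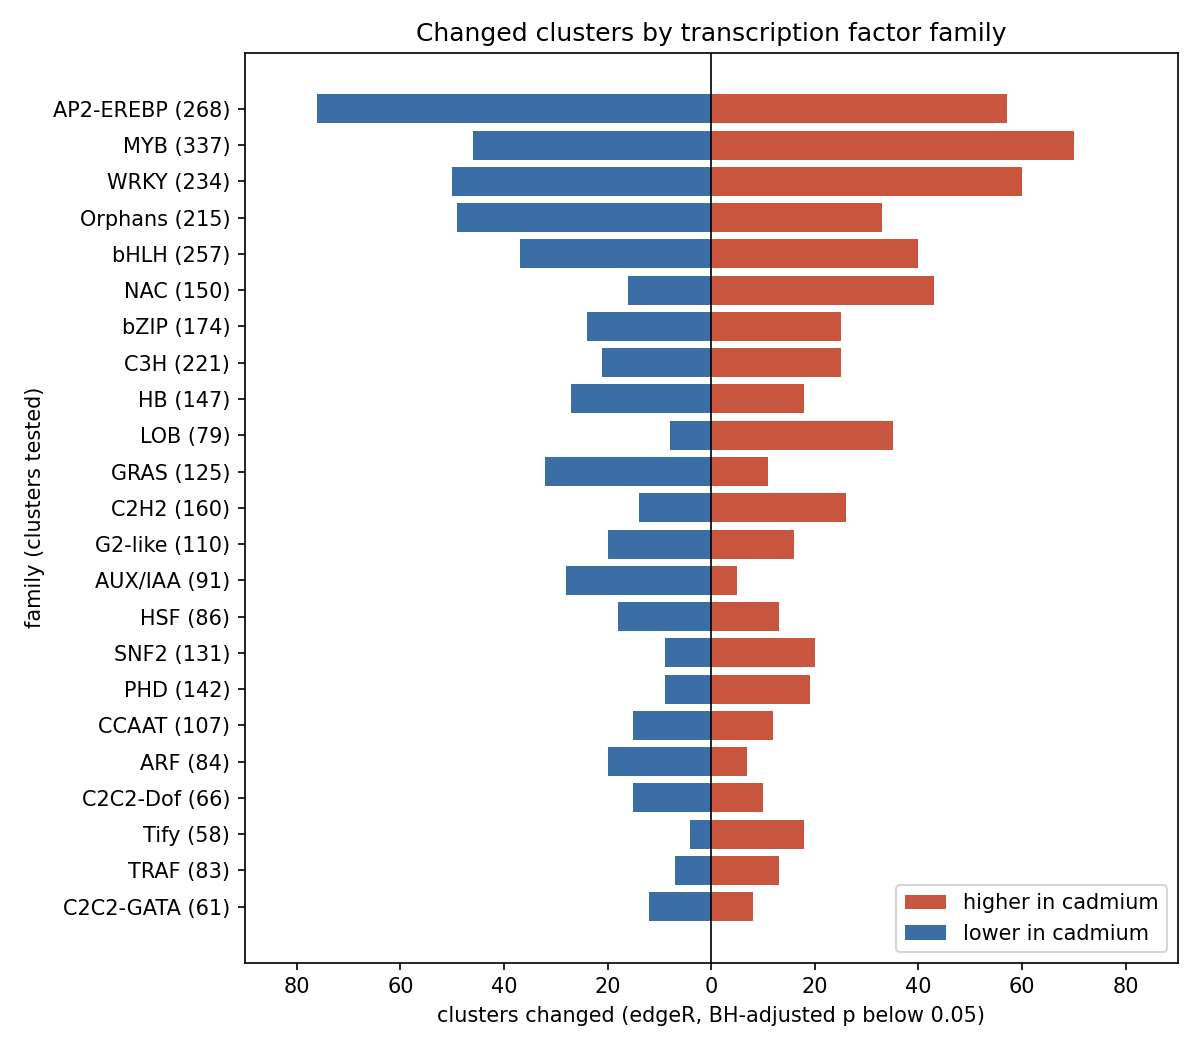
Clusters higher (right) and lower (left) in cadmium in each of the 23 families with at least 20 changed clusters, with the number tested in brackets. AP2-EREBP had 57 higher and 76 lower, NAC 43 higher and 16 lower, LOB 35 higher and 8 lower, GRAS 11 higher and 32 lower and AUX/IAA 5 higher and 28 lower. With whole-library totals the higher and lower counts changed order in MYB (60 and 68), WRKY (45 and 62), bHLH (32 and 62), bZIP (11 and 42), C3H (10 and 40), C2H2 (17 and 26), PHD (5 and 19) and TRAF (8 and 14), and were equal in SNF2 (14 and 14).

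Hormone-response lists fixed before the data were examined gave 2 group calls of 14 lists tested. The auxin response list, made up of AUX/IAA proteins and the auxin response factors (ARF) that they bind, had 12 clusters higher and 46 lower of 169, and 13 higher and 48 lower when adjusted over the list alone. Its median was −0.61, or −0.94 with whole-library totals (camera, Benjamini-Hochberg adjusted p = 0.0125, and adjusted p = 0.174 with an estimated correlation). IAA14 (Cluster-9033.96115) and IAA9 (Cluster-9033.87494) fell by 1.65 ± 0.1 and 1.75 ± 0.09 on the log2 scale (−1.16 for IAA9 with NR sums), and ARF9 fell from 679 ± 26.4 to 187 ± 34.3 CPM. ARF19, an activator with a known part in lateral root formation, rose from 435 ± 29.4 to 877 ± 107 CPM. A pair of ARF5 clusters went apart: Cluster-9033.119472 rose from 490 ± 34.7 to 1650 ± 175 CPM, and Cluster-9033.119473 fell from 138 ± 44.9 CPM to 0 in all 3 cadmium libraries, which is at least 156-fold lower against 3 counts over the group. Summed over their shared best hit, ARF5 counts were higher in cadmium (log2 fold change 1.1 with NR sums), so the fall of the second cluster is a change of that cluster and not of the summed gene.

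The jasmonate list had 16 clusters higher and 3 lower of 49, the same counts when adjusted over the list alone, with a median of 0.57 (camera, Benjamini-Hochberg adjusted p = 0.0307, and adjusted p = 0.405 with an estimated correlation). With whole-library totals 15 were higher and 7 lower, and the median was 0.17. Its tested members are mainly TIFY proteins, known as repressors of jasmonate response. TIFY 9 rose from 25.9 ± 3.46 to 294 ± 18.3 CPM and TIFY 10A from 491 ± 27.1 to 1450 ± 89.9 CPM. TIFY 4B fell from 47.3 ± 5.53 to 16.9 ± 3.53 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.0218), a call that ended when any of 5 of the 6 libraries was left out. Its log2 fold change was −1.48, or −2.2 with NR sums over 13 clusters (edgeR, Benjamini-Hochberg adjusted p = 3.89e-05). MYC2, which TIFY repressors bind and which stands in the bHLH list, fell by 1.48 ± 0.1 on the log2 scale. The jasmonate call ended without control replicate 1, without cadmium replicate 3 and after sums over the best protein hit (camera, Benjamini-Hochberg adjusted p = 0.0657), and both list calls ended when clusters changed over 32-fold were left out.

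Ethylene, abscisic acid and cytokinin regulators gave smaller groups. Of 20 clusters in the ethylene synthesis and signalling list, 8 rose and 2 fell (9 and 4 when adjusted over the list alone), with 4 higher and 4 lower under whole-library totals, and the list did not pass as a group (camera, Benjamini-Hochberg adjusted p = 0.271). ETHYLENE INSENSITIVE 3, the main activator of ethylene response, rose from 85.5 ± 16.9 to 379 ± 29.2 CPM, a log2 fold change of 2.15 that was 0.49 with NR sums. Of 22 clusters in the abscisic acid list 2 rose and 5 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.507), and protein phosphatase 2C 27 fell from 145 ± 21.8 to 44.6 ± 1.84 CPM. The annotated group of type A response regulators, which respond to cytokinin and dampen its signal, had 1 cluster higher and 11 lower of 21, with a median of −1.33, or 1 and 13 and −1.68 with whole-library totals (camera over 256 annotation terms, Benjamini-Hochberg adjusted p = 0.0133, and adjusted p = 0.816 with an estimated correlation). ARR5 fell from 803 ± 116 to 50.7 ± 11.2 CPM (log2 fold change −3.98, or −1.89 with NR sums), while the type B regulator ARR2, an activator of cytokinin response, rose from 283 ± 38.2 to 1560 ± 70.8 CPM (Cluster-9033.50181). Another ARR2 cluster (Cluster-9033.131779) fell from 125 ± 82.4 to 19.1 ± 4.53 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.0241), a call that ended when any of 5 of the 6 libraries was left out, counts summed over the Swiss-Prot hit of both were higher in cadmium, and its NR sum did not pass (−0.22).

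WRKY factors moved in both directions. Of 226 clusters in the WRKY list 60 rose and 47 fell, or 66 and 50 when adjusted over the list alone, and the group did not pass (camera, Benjamini-Hochberg adjusted p = 0.271). WRKY28 rose from 76.3 ± 3.25 to 798 ± 48 CPM and WRKY70 from 418 ± 22.8 to 3400 ± 282 CPM. All 9 changed clusters of the 11 annotated as WRKY33, a regulator of defence against fungi, fell, as did all 11 with whole-library totals (camera over annotation terms, Benjamini-Hochberg adjusted p = 0.0144, and adjusted p = 0.82 with an estimated correlation). The cluster among them with the smallest adjusted p (Cluster-9033.83741) fell from 3440 ± 368 to 1090 ± 27.5 CPM (log2 fold change −1.66, or −1.05 with NR sums). A WRKY22 cluster (Cluster-9033.80688) fell from 909 ± 120 to 226 ± 16.2 CPM, a log2 fold change of −2.01 that kept its direction and call with NR sums (−1.43), but counts summed over all clusters with that best Swiss-Prot hit were higher in cadmium. With whole-library totals the WRKY counts were 45 higher and 59 lower and the list's median changed from 0.2 to −0.15.

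Among MYB and NAC factors more clusters rose than fell, a lean that was smaller with whole-library totals (40 higher and 37 lower for MYB, 24 and 21 for NAC). Of 211 clusters in the MYB list 47 rose and 24 fell, or 48 and 25 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0708), with a median of 0.28 that turned to −0.07 with whole-library totals. The annotated group of plant MYB proteins passed, with 62 higher and 20 lower of 202 and a median of 0.75, or 54 and 34 and a median of 0.4 with whole-library totals (camera over annotation terms, Benjamini-Hochberg adjusted p = 0.0137, and adjusted p = 0.687 with an estimated correlation). RAX3 (Cluster-9033.9674) rose by 4.48 ± 0.12 on the log2 scale, and MYB44, known from abscisic acid and drought responses, rose from 914 ± 22.5 to 2780 ± 186 CPM. Of 110 clusters in the NAC list 33 rose and 14 fell, or 35 and 14 when adjusted over the list alone, with a median of 0.34, or 0.03 with whole-library totals (camera, Benjamini-Hochberg adjusted p = 0.15). ATAF2 and NAC domain-containing protein 2 rose from 933 ± 106 to 4730 ± 292 CPM and from 776 ± 32.5 to 3740 ± 73.2 CPM. A NAC41 cluster fell from 115 ± 1.55 to 24.8 ± 4.51 CPM, a change that did not pass with NR sums (−0.25). None of the 3 annotation terms was called after such summing, but terms with fewer than 10 summed proteins were not tested there.

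Ethylene-responsive factors formed the list with the most changed clusters, 57 higher and 70 lower of 258, or 61 and 80 when adjusted over the list alone and 47 and 93 with whole-library totals (camera, Benjamini-Hochberg adjusted p = 0.507). ERF106 (Cluster-9033.101662) rose from 269 ± 13.1 to 2060 ± 68.7 CPM and ERF2 from 443 ± 49 to 2110 ± 148 CPM. ERF5 fell from 8690 ± 175 to 2720 ± 95.8 CPM, and DREB1A, a regulator of cold and drought responses, fell from 1080 ± 42.5 to 244 ± 7.02 CPM. Of 169 clusters in the bHLH list 31 rose and 20 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.507), a balance that turned to 25 and 38 with whole-library totals. bHLH96 rose from 751 ± 40 to 3160 ± 156 CPM.

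Heat stress factors counted 13 higher and 14 lower of 79, also when adjusted over the list alone, but 9 higher and 19 lower with whole-library totals (camera, Benjamini-Hochberg adjusted p = 0.677). HSFA1a rose from 26.2 ± 8.1 to 400 ± 23.2 CPM and HSF24 from 1020 ± 75.3 to 3030 ± 111 CPM. HSFA3 (Cluster-9033.86180) fell by 3.69 ± 0.13 on the log2 scale and HSFA4a from 1360 ± 183 to 407 ± 13.7 CPM (log2 fold change −1.74, or −0.63 with NR sums). Of 78 clusters in the bZIP list 9 rose and 12 fell, also when adjusted over the list alone, or 5 and 21 with whole-library totals (camera, Benjamini-Hochberg adjusted p = 0.677). The endoplasmic reticulum stress factors bZIP60 and bZIP17 went apart, bZIP60 from 374 ± 30.3 to 790 ± 34.9 CPM and bZIP17 from 3510 ± 70.1 to 1190 ± 77.5 CPM.

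The C2H2 zinc finger list, whose word match also takes in CONSTANS-like proteins, had 23 clusters higher and 26 lower of 103, or 23 and 27 when adjusted over the list alone and 18 and 33 with whole-library totals (camera, Benjamini-Hochberg adjusted p = 0.628). ZAT11 rose from 106 ± 17.4 to 1220 ± 148 CPM, and a homolog of STOP1, a regulator of proton and aluminium tolerance in roots, rose from 454 ± 29.8 to 1050 ± 10.5 CPM. Of 27 clusters in the MAP kinase and calcium signalling list 7 rose and 5 fell, or 8 and 6 when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.819). The median of that list was 0.15 and its mean −0.62, with camera's direction up, and under whole-library totals the counts were 6 higher and 8 lower and the median −0.19. Its member CAMTA3, a calmodulin-binding activator, rose from 287 ± 17 to 1090 ± 83.7 CPM (Cluster-9033.69704). Another CAMTA3 cluster (Cluster-9033.72419) fell from 130 ± 46 to 41.8 ± 3.58 CPM, while counts summed over their best hit were higher in cadmium (log2 fold change 0.93 with NR sums, where the rising cluster alone had 1.93). The kinase CIPK23, which regulates potassium and nitrate uptake, fell from 1570 ± 173 to 298 ± 66.3 CPM. In the cell cycle list 0 clusters rose and 3 of 17 fell, also when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.271, with 0 higher and 10 lower with whole-library totals). In the GRAS family CIGR1 fell from 4760 ± 267 to 779 ± 28.8 CPM (log2 fold change −2.61, or −1.11 with NR sums) and Scarecrow-like protein 8 from 2400 ± 64.5 to 671 ± 13.6 CPM.

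**Figure D3:**
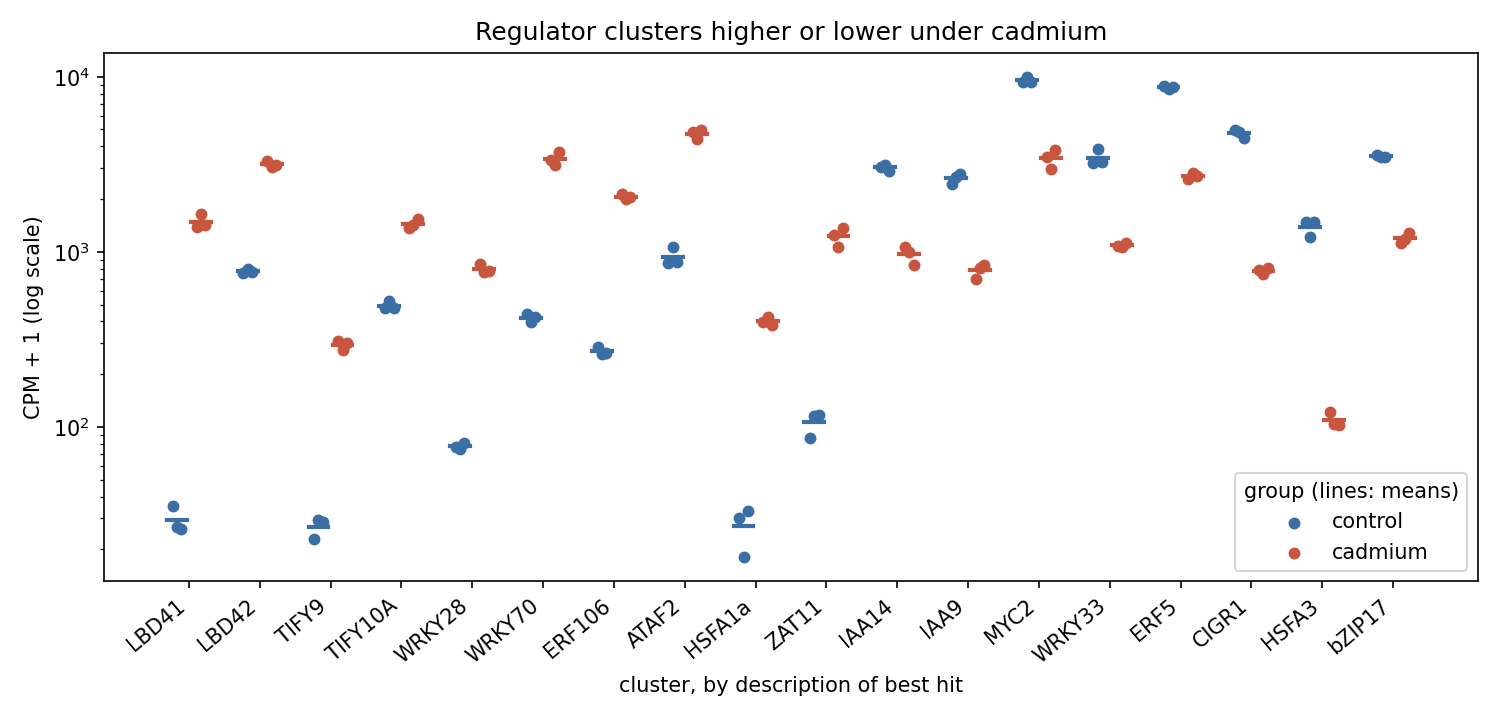
CPM + 1 on a log axis in each library for 18 named clusters (points: libraries, lines: group means, n = 3 per group). The 10 clusters on the left, LBD41 to ZAT11, were higher in every cadmium library than in every control library, and the 8 on the right, IAA14 to bZIP17, were lower.

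Pseudo-response regulators, which form part of the plant circadian clock, had the highest share of changed clusters among the families tested, 3 higher and 6 lower of 11 (81.8%). APRR7 (Cluster-9033.87556) fell by 6.41 ± 0.19 on the log2 scale and PRR95 (Cluster-9033.56804) from 502 ± 71.8 to 1.98 ± 3.43 CPM, while PRR1 rose from 560 ± 8.38 to 1090 ± 37.5 CPM. REVEILLE 1, a MYB-like clock output regulator, fell from 192 ± 26.6 to 19.8 ± 6.57 CPM. In the CONSTANS-like family 5 clusters rose and 7 fell of 15, and CONSTANS-LIKE 5 fell from 1000 ± 85.9 to 95.7 ± 18.9 CPM. A CONSTANS-LIKE 9 cluster grouped with other regulators (Cluster-9033.105807) rose from 185 ± 56 to 1950 ± 83.6 CPM. Neither family passed as a group (camera, Benjamini-Hochberg adjusted p = 0.795 and 0.97). Among RWP-RK regulators of nitrate response, NLP4 rose from 144 ± 8.43 to 870 ± 123 CPM and NLP7 fell from 307 ± 26.4 to 120 ± 24.2 CPM (log2 fold change −1.36, or −0.4 with NR sums).

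**Figure D4:**
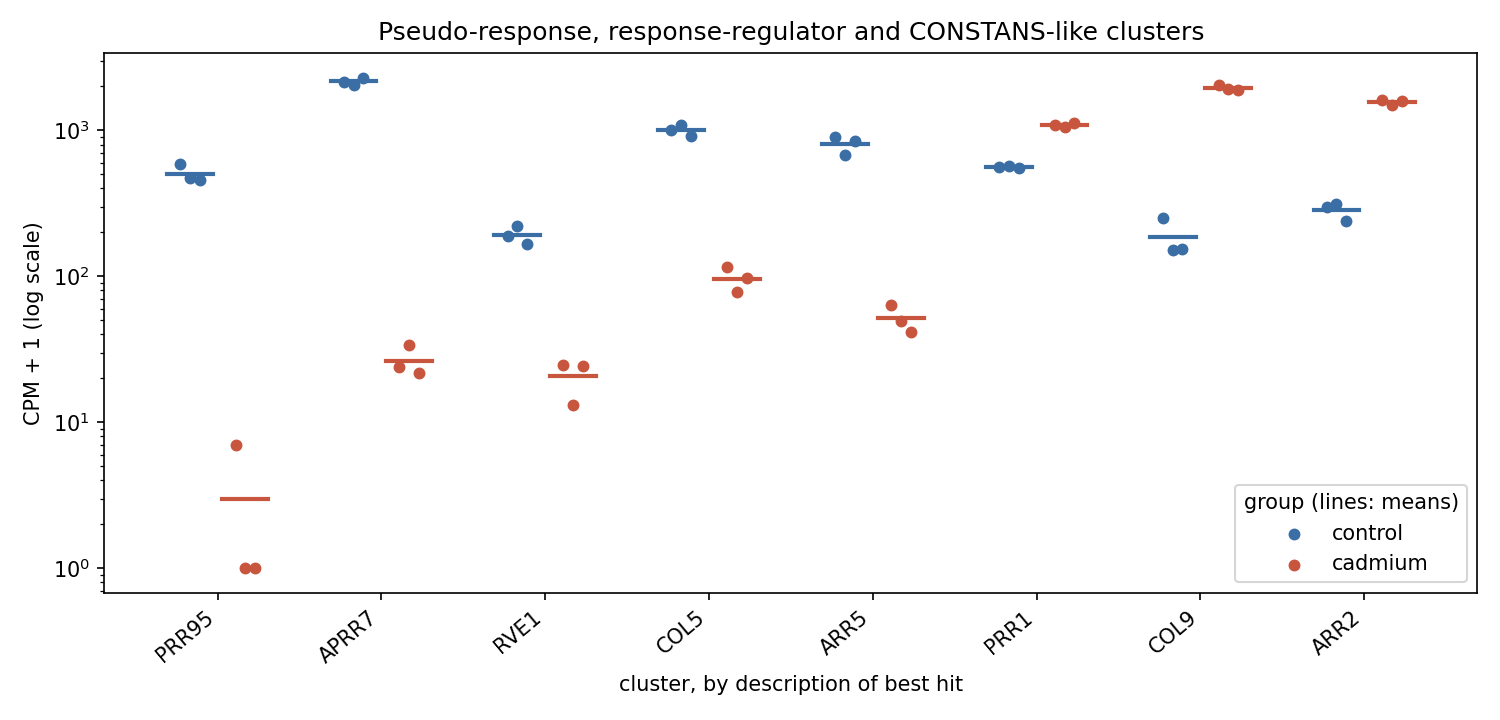
CPM + 1 on a log axis in each library for 8 clusters named as pseudo-response regulators, REVEILLE 1, CONSTANS-like proteins and response regulators (points: libraries, lines: group means, n = 3 per group). PRR95, APRR7, RVE1, COL5 and ARR5 were lower in every cadmium library than in every control library, and PRR1, COL9 and ARR2 were higher.

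Some clusters were counted in all libraries of 1 group and in none of the other. In cadmium 32 higher clusters had 0 counts in all control libraries, and 56 lower clusters had 0 in all cadmium libraries. Fitted fold changes of such clusters depend on the prior count, so bounds against 3 counts over the group at 0 are given, and most of those named here changed far less with NR sums. A cluster named for a ribonuclease H protein and listed as bHLH (Cluster-9033.120154) was at least 692-fold higher at 541 ± 39.8 CPM, while 2 other clusters of that symbol fell and the NR sum had a log2 fold change of 0.83. Sin3-like 4, a corepressor subunit, was at least 267-fold higher at 208 ± 38.8 CPM, with 0.96 after NR sums, and a cluster of the mitochondrial protein WHY2 at least 81.8-fold higher at 63.9 ± 16.8 CPM (Cluster-9033.93881), with 0.8 after NR sums. Another WHY2 cluster, with a different best NR protein (Cluster-9033.93884), fell from 105 ± 6.76 to 40.3 ± 2.36 CPM. A cluster of the histone acetyltransferase HAM2 was at least 157-fold higher at 123 ± 27.2 CPM, a change that did not pass with NR sums (0.2).

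Among the clusters lost in cadmium, CONSTANS-LIKE 10 was at least 193-fold lower from 170 ± 43.8 CPM, while 2 other clusters of that symbol rose and the NR sum had a log2 fold change of −0.73. WRKY20 was at least 86.8-fold lower from 76.5 ± 43.3 CPM and histidine kinase 5, a cytokinin-receptor relative, at least 76.8-fold from 67.7 ± 5.38 CPM, with log2 fold changes of −0.54 and −0.8 after NR sums. A cluster of zinc finger protein C3H39 was at least 105-fold lower from 92.4 ± 25.8 CPM, and was alone under its best NR protein, while counts summed over its Swiss-Prot hit were not lower. Calcium uniporter protein 5, listed in the LOB family, was at least 198-fold lower from 175 ± 161 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.0387), a call that ended when any of 5 of the 6 libraries was left out. Its log2 fold change was −3.88 with NR sums.

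Of the 39 lists fixed before the data were examined, 25 had fewer than 5 tested clusters and were not tested as groups, and 18 of the 39 had no cluster among these regulators. In the list of heat shock proteins and chaperones 1 of 2 tested clusters, a DnaJ homolog (Cluster-9033.124784), passed with a small rise of 0.26 ± 0.08 (SE) on the log2 scale (edgeR, Benjamini-Hochberg adjusted p = 0.0493). That call ended when any library was left out, and with whole-library totals the log2 fold change was −0.08 (adjusted p = 0.489). The root cell-type lists of xylem and vascular markers and of root hair and root cap markers had 4 tested clusters each, with 0 changed by edgeR and 0 at an unadjusted p below 0.05. By the same test 0 of 2 heavy metal-associated chaperones, 0 of 2 class III peroxidases and 0 of 3 ABC transporters changed, with 1 ABC transporter at an unadjusted p below 0.05. The photosynthesis list had 2 clusters, with 0 tested.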

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

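Chosen after seeing the data were the sums over the best NR protein, the authors' ratio scale, the sets without clusters changed over 32-fold, all alternatives for families and the leave-one-out fits for terms.

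The count of 1476 changed clusters stayed within 1.5 times under RLE size factors (1479), whole-library totals (1640), no filter (1250), the stricter filter (1492), removal of non-plant NR hits (1476), the authors' ratio scale (1476), the DESeq2 Wald test (2196), and limma-trend on FPKM + 1 (2149) and FPKM + 0.1 (2041). With each library left out it ran from 1136 to 1215, and the count at 2-fold or more from 868 to 942. Sums count proteins and not clusters: Swiss-Prot sums gave 850 changed of 1502 proteins and NR sums 1249 of 2070. The 2-fold count of 1033 became 1561 with DESeq2, which tested 6592 clusters, 401 with Swiss-Prot sums and 674 with NR sums.

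The labels do not say whether a replicate number marks a shared experiment. Residuals of libraries with the same number correlated at 0.005, 0.029 and −0.004. This shows no pairing, but 3 libraries per group cannot exclude one. With the replicate number as a block, 886 clusters changed, 673 of them at least 2-fold, and camera called 1 list (auxin response), 7 families, the reported 4 among them, and 4 terms. The block also ended the calls of TIFY 4B (Cluster-9033.137644, adjusted p = 0.0813), WHY2 (Cluster-9033.93881, 0.0545), ARR2 (Cluster-9033.131779, 0.0891), histidine kinase 5 (Cluster-9033.27395, 0.0534) and the DnaJ homolog (Cluster-9033.124784, 0.138) in edgeR with Benjamini-Hochberg adjustment.

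An estimated correlation gave 0 lists, 0 families and 0 terms. Fry, which tests whether a set's genes move on balance one way and does not compare them with other genes, called 11 lists and 39 families. With the preset correlation NR sums gave 1 list (auxin response), 1 family (AUX/IAA) and 0 terms. Groups below the minimum size in summed proteins were not tested there. Without clusters changed over 32-fold, camera called 0 lists and 6 families, the reported 4 among them. The cause was not tested. With a library left out, lists ranged from 1 to 3: jasmonate was lost without control replicate 1 (1 list) and without cadmium replicate 3 (1 list), and MYB was added without control replicate 2 (3 lists). Families ranged from 4 to 7, with 7 without control replicate 2 and without cadmium replicate 1, the reported 4 among them each time. Terms ranged from 3 to 3.

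For the 67 named clusters 1158 of 1206 values kept direction and call, 38 kept direction but not the call, and 10 reversed. Of these 7 came with sums, which by construction add other clusters of the same name: ARF5 Cluster-9033.119473 from −10.38 to 0.75 (Swiss-Prot) and 1.1 (NR), CAMTA3 Cluster-9033.72419 from −1.63 to 1.08 (Swiss-Prot) and 0.93 (NR), ARR2 Cluster-9033.131779 from −2.71 to 0.99 (Swiss-Prot), WRKY22 from −2.01 to 0.55 (Swiss-Prot) and C3H39 from −9.8 to 0.3 (Swiss-Prot, not past the test). NR sums kept WRKY22 (−1.43), and C3H39 was alone under its NR protein. The other 3 were the DnaJ homolog (Cluster-9033.124784), from 0.26 to −0.08 with whole-library totals, −0.07 with FPKM + 1 and −0.08 with FPKM + 0.1, none past the test. LATERAL ROOT PRIMORDIUM 1 was 0.42 with whole-library totals, 0.39 with FPKM + 1 and 0.4 with FPKM + 0.1, none past the test. TIFY 4B (Cluster-9033.137644) lost its call without any library but cadmium replicate 2 (adjusted p 0.057 to 0.0722), calcium uniporter protein 5 (Cluster-9033.82043) without any but control replicate 1 (0.0777 to 0.0996) ARR2 Cluster-9033.131779 without any but control replicate 2 (0.0664 to 0.085) and the DnaJ homolog (Cluster-9033.124784) without any library (0.0826 to 0.138), by edgeR with Benjamini-Hochberg adjustment. In the simulation 9.5% of 2-fold changes were recovered, so small changes can be missed. A smaller share of clusters changed there than in the data, so the rate need not hold for the data.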

Other observations

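Chosen after the result was seen were the tests of shallow counting, of clusters present in some plants whatever the treatment, of sums over the protein for clusters changed over 32-fold with an oppositely changed relative and for the clock genes, of scaling and of harvest hour for clock genes, and of transcripts outside the regulators, as well as the clock gene list itself.

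Some families that did not pass as groups overlap the lists reported for hormones and calcium. TIFY regulators had 18 clusters higher and 4 lower of 58, or 17 and 8 with whole-library totals (camera, Benjamini-Hochberg adjusted p = 0.0527), and auxin response factors 7 higher and 20 lower of 84, or 5 and 28 (adjusted p = 0.0743). The calmodulin-binding CAMTA family had 5 higher and 1 lower of 16, or 4 and 3 with whole-library totals (camera, Benjamini-Hochberg adjusted p = 0.247). The cytokinin-response ARR-B family had 7 higher and 2 lower of 29, or 6 and 5 with whole-library totals, and the ethylene-response EIL family 7 higher and 2 lower of 16, or 4 and 4 (camera, Benjamini-Hochberg adjusted p = 0.329 for each). RWP-RK regulators of nitrate response had 9 higher and 4 lower of 52, or 7 and 6 with whole-library totals (camera, Benjamini-Hochberg adjusted p = 0.0519). HMG-box proteins had 1 higher and 7 lower of 30, or 1 and 11 with whole-library totals (camera, Benjamini-Hochberg adjusted p = 0.0752).

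Clock regulators differed by kind. Clusters like PRR9 and PRR95, morning genes in other plants, had 0 higher and 7 lower of 7, and those like PRR7 0 higher and 4 lower of 5. Several clusters share a best NR protein, so these are not counts of separate genes. The NR sums had log2 fold changes of −6.65 and −1.92 for PRR9 and PRR95, and −4.7 and −3.28 for PRR7. Clusters like PRR1, an evening gene, had 3 higher and 0 lower of 6. REVEILLE clusters had 1 higher and 3 lower of 9, LUX-like clusters 2 higher and 3 lower of 13, cyclic dof factors 3 higher and 5 lower of 17, and those like PRR5 0 higher and 1 lower of 2. The PRR5-like clusters share the PRR95 protein whose sum was −1.92, and the 3 lower LUX-like clusters share a protein (−1.06). Lower cyclic dof clusters Cluster-9033.50097 and Cluster-9033.37239 belong to a protein whose NR sum was higher in cadmium (0.8). Of 3 clusters like LHY 0 passed edgeR's test, but their NR sum passed with a log2 fold change of 0.98 (edgeR, Benjamini-Hochberg adjusted p = 0.00365). For GIGANTEA, ELF3 or ELF4, 0 clusters were tested.

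In total 142 clusters changed over 32-fold by the fit (110 with bounds for groups at 0), 56 higher and 86 lower. The higher group had a median of 50.7 CPM, and the 88 clusters at 0 in the lower group had a median bound of 40.9-fold. These clusters had already passed the count filter and the adjusted p, which favours high values, so this is no independent test of shallow counting. Of 37 clusters at 0 in exactly 3 libraries and with at least 50 counts in each of the others, 73% followed the groups. An even spread over the 20 arrangements gives 10%. All 37 come from the same 6 libraries and are not independent, and plants that differ between the groups by descent would give the same. In addition, 69 clusters were at 0 in 1 control library and 63 in 1 cadmium library with at least 50 counts in both others of the group. These counts therefore cannot decide about alleles carried by some plants whatever the treatment. Of the clusters changed over 32-fold, 26 had an oppositely changed relative, against a median of 40 after fold changes were shuffled. Shuffling also removes any shared change of clusters of the same protein, and such a change lowers the count in the data. The comparison therefore cannot decide about reads moving between near-identical clusters. A move of reads between clusters of the same best NR protein, as the whole cause, would leave sums over that protein unchanged. Moves between clusters with different best NR proteins would change these sums too, so the sums cannot decide about them. Without an oppositely changed relative, 82.2% of those that share their protein with another cluster (89 proteins) stayed changed in their direction. Their median log2 fold change in that direction was 2.25 beside 7.58 before (5.52 at the bounds). Of the 26 with an oppositely changed relative 3 stayed changed in their direction. Both sets were picked by their relatives, so neither share can tell a move of reads apart from a change of the gene. Over both sets, 67.7% of 127 stayed, a limited argument against a move of reads within the same NR protein as the whole cause. Sums also carry changes of the other clusters, and 1249 of 2070 proteins changed with NR sums. The median over the 127 was 1.26 beside 7.69 before (5.64 at the bounds), and 17 stayed over 32-fold. Moving reads as a part of the cause, and moves between different NR proteins, thus stay open.

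Of the 62 clock clusters 32 changed (51.6%), in a list written after the changes of pseudo-response regulators had been seen, so that no test of this share is given. Of the changed clock clusters, 29, from 14 proteins, share their NR protein with another cluster. Against reads moving within the same NR protein as the whole cause, 26 of these 29 stayed changed in their direction after sums. Moves between different NR proteins are not covered by this. Over all 29 the median log2 fold change in that direction was 1.92 beside 3.09 before. The other 3, from BOA and cyclic dof factor 2, had the opposite direction after sums, and for these a move of reads and a change of the gene cannot be told apart, since they were picked by that outcome. Against scaling, the changed clock clusters had a median absolute log2 fold change of 3.11 beside a shift of −0.347. Another hour of harvest could give the pattern, since 17 changed clusters of day-phased genes were lower and 3 higher, although by protein the lean was weaker (7 of 10 summed day-phased proteins lower and 3 higher, and 13 lower and 9 higher over all clock proteins), and it cannot be told apart from a response to cadmium, because the hour is not given in the sources used here.

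The lower share of regulators in the cadmium libraries does not rest on the most abundant clusters: without the top 100 the share was 4.4% ± 0.042 against 3.75% ± 0.082 (SD, n = 3), a fall of 14.8% beside 17.1% with all clusters. The median log2 fold change on the whole-library scale was −0.426. A rise of a few abundant transcripts outside the regulators could give this, and it cannot be told apart from a broad fall of regulators, since those transcripts were not analysed here.

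The 6 libraries allow 10 splits into 3 and 3, so that a share under 0.05 cannot be reached, and 1 split, the real one, gave counts as large in each of 5 cases. The real split gave 1476 changed clusters and the highest other split 0, and for changes of at least 2-fold 1033 and 0. Camera called 4 families in the real split and 3 in the highest other, 2 lists and 1, and 3 terms and 0.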
